A study of Mus musculus with 6 samples.

How the data were processed

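RNA from mouse brain tissue, labelled as paraventricular nucleus of the hypothalamus, was measured by mRNA sequencing in 6 libraries, 3 from wild-type mice (WT) and 3 from mice with a knockout of Adam17 in glutamatergic neurons (KO). Each genotype has 2 male libraries, replicates 1 and 2, and 1 female library, replicate F1. Per the labels' protocols, total RNA was extracted with a TRIzol-type kit and libraries were made with a kit for mRNA. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic 0.36 and bedtools 2.26.0 were used. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here.

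The authors deposited, per the file headers, a whole-number count, a TPM value and an FPKM value for each of 51826 Ensembl genes in each library. The deposited counts were used as they stand for the tests. The deposited TPM values were used only for an alternative test, and the deposited FPKM values, a constant multiple of TPM within a library, were only checked. No column of per-sample values was left over. A side column of the deposited table holds 226 entries, 220 distinct symbols of chloride, potassium and sodium channels and transporters, with no stated origin, and it was used only as an extra gene list. Of the gene identifiers, 51633 (99.6%) matched the GENCODE M21 annotation of GRCm38, and 94.2% of these had identical coordinates in it, so coordinates are given as the deposited table gives them and read as GRCm38.

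Total counts per library were 42952227, 40652708 and 54421330 for WT replicates 1, 2 and F1, and 35114426, 45355375 and 39455021 for KO replicates 1, 2 and F1. At these depths 3 counts, the floor used for a gene with no count, correspond to between 0.055 and 0.085 CPM, that is counts scaled to the library total. The floor covers counting error only.

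Genes were kept with filterByExpr by genotype, which left 18956, and library sizes were scaled by the trimmed mean of M values (TMM). Genotype effects were tested with edgeR 4.0.16 (R 4.3.3), using robust quasi-likelihood fits (glmQLFit and glmQLFTest) with genotype and sex as terms, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The sex effect came from the same fit, and the interaction of genotype and sex from a fit with their product added, which leaves 2 residual degrees of freedom. Expression levels are CPM with TMM scaling, given as mean ± SD over 3 libraries, and fold changes are log2 values, KO minus WT unless said otherwise, with standard errors (SE). Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F statistic.

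Gene lists for cell types, brain regions and pathways, 40 in all, were fixed before the data were examined, as were the tests, the rule for naming genes and most alternatives. Lists with at least 3 tested members (39) were tested with camera from limma 3.58.1 on voom values with the same terms and a preset correlation between genes of 0.01, adjusted over the lists. The same lists were tested with a correlation estimated from the data and with fry. Small lists for cerebellum, monoamine neurons of the midbrain and output neurons of the olfactory bulb were added after the data had been seen, and their genes are given only as values per library and log2 fold changes.

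Named genes were chosen by rule. Adam17 came first, followed by up to 12 genes per direction past the threshold with a mean of at least 1 CPM and no overlap between the genotypes, gene models without a proper name being only counted. Where fewer than 10 were found in a direction, genes with the smallest p filled up to 10, with no minimum level and whether or not the genotypes overlapped. A gene that this rule picked is not reported here. Each list described adds up to 4 members past the threshold or, with none, up to 2 members with the smallest p. Agtr1a, Slc17a6, Slc12a5, Slc12a2, Cx3cl1, Cx3cr1, Ccl2, Ccl5, Cxcl12, Avp, Oxt and Crh were always included. Other genes named were chosen after their values were seen.

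Alternatives were DESeq2 size factors in edgeR, library totals without scaling, other filters on low counts, voom with sample quality weights, DESeq2 1.42.0 with its Wald test, models without sex or with the replicate number as a block, males only, protein-coding genes only, limma-trend on log2(TPM + 1), and leaving out each library in turn. With sex as a term, leaving out either female leaves the genotype contrast of the males, so these 2 fits and the males alone are 1 alternative. Some settings were chosen after seeing the data, namely leaving out WT replicate F1 together with KO replicate 1, leaving out mitochondrial genes, and a covariate made of the mean of the cortex and hippocampus list. The fit without WT replicate F1 and KO replicate 1 has no sex term. Its only female library is KO replicate F1, so a sex difference enters its genotype contrast.

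The gene test was tested on simulated counts for the KO versus WT comparison with 18660 genes. It recovered 57 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 15 calls among genes that had not been changed and 0 recovered in the wrong direction. With no gene changed, 2 of 18657 genes and 0 lists were called. In the run with changed genes the immediate early list was also shifted, by 0.4. There 2 lists were called, the shifted list and 1 that had not been shifted. The simulated genes were drawn independently, so the list counts say nothing about lists whose genes vary together. The recovery counts hold for many genes changed at once, which eases the adjusted threshold. The labels do not state that each library comes from a separate animal, so p-values measure the spread between these libraries, which may be technical.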

Results

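Messenger RNA of tissue labelled as paraventricular nucleus, the hypothalamic nucleus that holds vasopressin, oxytocin and presympathetic neurons, was sequenced in 3 WT libraries and 3 libraries from mice lacking ADAM17 in glutamatergic neurons. ADAM17 is a membrane protease that sheds cytokines and growth factors from the cell surface. The title of the series names angiotensin II, microglia and chemotactic signalling, but the labels give no angiotensin treatment, and the stated comparison is KO against WT. Libraries held between 35114426 and 54421330 counts. Mitochondrially encoded genes took 7.26%, 7.22% and 7.64% of the counts in WT replicates 1, 2 and F1, and 20.63%, 9.2% and 7.8% in KO replicates 1, 2 and F1. In all 6 libraries the levels of Xist and of the Y-linked genes matched the labelled sex.

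The comparison asked how loss of ADAM17 in glutamatergic neurons affects gene expression in this tissue. Adam17 itself (ENSMUSG00000052593, chromosome 12, 21323509 to 21373632, minus strand, GRCm38) stood at 16.6 ± 0.91 CPM in WT and 14.6 ± 0.72 CPM in KO (SD, n = 3 each). Per library it was 17.1, 17.2 and 15.6 CPM in WT replicates 1, 2 and F1, and 15.4, 14.6 and 13.9 CPM in KO replicates 1, 2 and F1. All 3 KO values lay below the lowest WT value, but the log2 fold change of −0.19 (SE 0.11) did not pass the test (edgeR adjusted p = 0.747). The values cover the whole gene and all cell types of the tissue, the labels do not say which exon is deleted, and the gene overlaps Iah1 at its end, so the labels were not checked at the level of the deletion.

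Noct rose in the KO libraries. It encodes nocturnin, a phosphatase with rhythmic expression, and lies on chromosome 3 (51224447 to 51251644, plus strand). Its level was 17.1 ± 0.69 CPM in WT and 68.5 ± 10.3 CPM in KO (SD, n = 3 each), a log2 fold change of 2.0 (SE 0.11). The 3 WT libraries lay between 16.3 and 17.5 CPM and the 3 KO libraries between 57.3 and 77.5 CPM. Gm38357, a gene model inside Noct, stood between 0.33 and 0.54 CPM. The neighbouring genes Elf2 and Setd7 had log2 fold changes of 0.07 and 0.07, and neither passed the test. Noct was the only gene of 18956 past the threshold in this fit (edgeR adjusted p = 0.0152), with 1 gene higher and 0 lower. At an unadjusted p under 0.05 there were 1210 genes, 730 higher and 480 lower, where 948 would be expected by chance, and 2641 genes (13.9%) had no overlap between the genotypes, where chance gives 10%. Other groupings of the libraries into 3 and 3 gave 4444 and 1203 genes at an unadjusted p under 0.05, and the rest 308 to 571. DESeq2 called 75 genes, 50 higher and 25 lower. The Noct call was lost without WT replicate 1 (adjusted p = 0.28), WT replicate 2 (0.295) or KO replicate 2 (0.121), where 0 genes passed, while 20, 7 and 15 genes passed without WT replicate F1, KO replicate 1 and KO replicate F1, and the Noct log2 fold change lay between 1.94 and 2.09 in these 6 fits. Because sex is a term, the fits without WT replicate F1 and without KO replicate F1 both rest on the 4 male libraries for genotype, as do the males alone (18 genes).

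The genes next in order of p did not pass in the edgeR fit and are given as values. On the higher side, Slc38a1, a neutral amino acid transporter that carries glutamine, stood at 89.8 ± 6.41 CPM in WT and 211 ± 37.4 CPM in KO (SD, n = 3 each; log2 fold change 1.23, SE 0.12, edgeR adjusted p = 0.128). Tnpo1, a nuclear import receptor, stood at 32.8 ± 2.98 and 73.1 ± 8.17 CPM (1.16, SE 0.13, adjusted p = 0.165), and Dcaf17, a substrate receptor of a ubiquitin ligase, at 3.95 ± 0.38 and 10.1 ± 2.16 CPM (1.33, SE 0.16, adjusted p = 0.165). Hif3a, a hypoxia-inducible factor subunit, had a log2 fold change of 0.83, the transcription factor Egr2 of 1.16, the interneuron transcription factor Dlx2 of 0.65, the retinol-binding protein receptor Stra6 of 0.66 and the low-abundance gene Frrs1 of 1.77. Pcdhb21 stood at 0, 0 and 0.46 CPM in WT replicates 1, 2 and F1 and at 0.80, 0.36 and 4.80 CPM in KO replicates 1, 2 and F1, and overlaps another tested protocadherin gene, so its count is uncertain. On the lower side, Col25a1, a transmembrane collagen of neurons, stood at 70.7 ± 5.77 CPM in WT and 35.9 ± 4.08 CPM in KO (log2 fold change −0.98, SE 0.11, edgeR adjusted p = 0.165). Cdkn2d, an inhibitor of cyclin-dependent kinases, was at 24.5 ± 1.83 and 13.8 ± 1.81 CPM (−0.83, SE 0.13, adjusted p = 0.568). Log2 fold changes were −0.90 for Baiap3, −0.75 for the neuronal globin gene Ngb, −0.67 for the intermediate filament protein gene Synm and −0.52 for Phlda3, and Daw1 stood at 0.71, 0.68 and 0.34 CPM in WT replicates 1, 2 and F1 and at 0.21, 0.09 and 0.02 CPM in KO replicates 1, 2 and F1. The gene model listed as Rnf26 (−3.31) overlaps other tested genes, among them Usp2. Snhg4 (−0.86) overlaps the tested gene model Gm28285, so both are uncertain. Tnpo1, Dcaf17, Stra6, Baiap3 and Synm each overlap another tested gene too, and their counts are uncertain to that extent because the counting strand is not given. The KO and WT libraries overlapped in Egr2, Pcdhb21, Ngb and Baiap3 and not in the others, and the choice by smallest p favours a lack of overlap. DESeq2 called 18 of the 20 genes chosen for their p, Noct included.

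**Figure D1:**
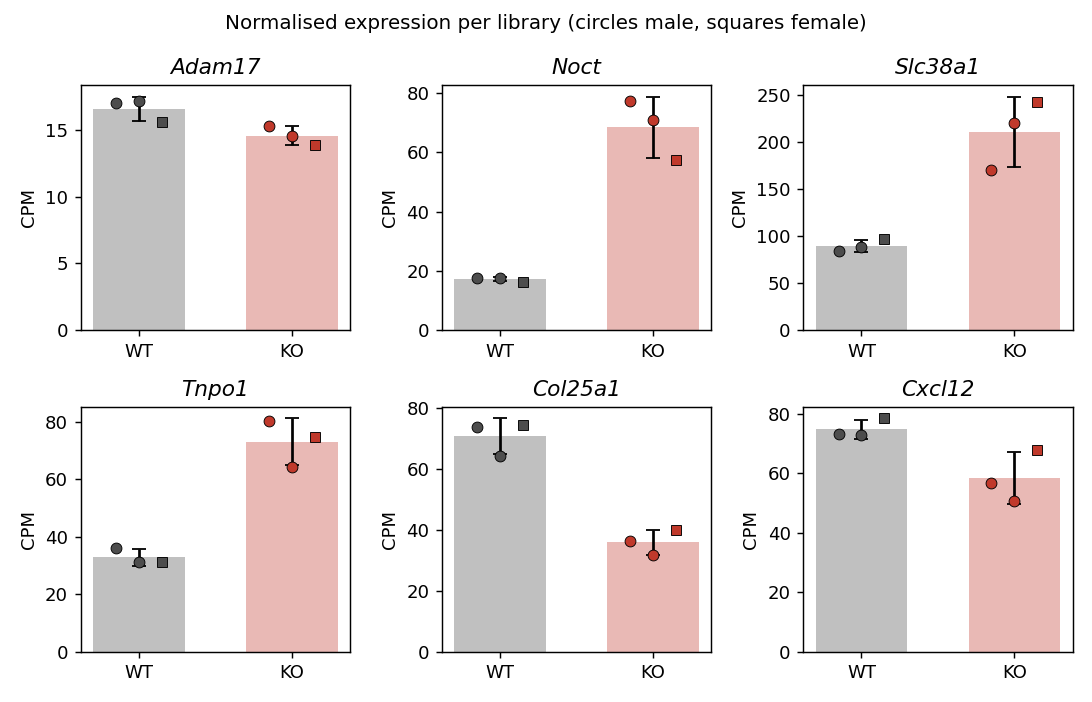
Normalised expression (CPM, from 0) of 6 genes in WT and KO. Bars are means, error bars SD over 3 libraries, circles male libraries and squares female libraries. Noct stood at 17.1 CPM in WT and 68.5 CPM in KO, and Adam17 at 16.6 and 14.6 CPM.

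Of the 39 gene lists tested, 9 passed with the preset correlation, 6 higher and 3 lower in KO. Immediate early genes, which neurons switch on with activity, passed as a group, higher in KO (camera adjusted p = 4.31e-08). Of 23 members 21 lay above 0, with a median log2 fold change of 0.39. The adjusted p was 0.574 with an estimated correlation, and 0 of the 39 lists passed with estimated correlations or with fry. Egr2 stood at 3.56 CPM in WT and 8.24 CPM in KO (log2 fold change 1.16, SE 0.18), and Nr4a1 at 47.7 and 69.0 CPM (0.56, SE 0.12). Egr1 (0.67), Egr3 (0.71), Egr4 (0.50), Fosb (0.55), Npas4 (0.59), Dusp1 (0.59) and Homer1 (0.40) were similar, whereas Arc (0.01) and Btg2 (−0.01) lay near 0. The low-abundance Atf3, at 0.67 CPM in WT and 0.45 CPM in KO, lay below 0 (−0.65, SE 0.34). No member passed over all genes tested by edgeR, and 9 passed adjusted over the list alone. The mean log2 CPM of the list was 4.34 and 4.53 in the male WT libraries against 4.77 and 4.78 in the male KO libraries, and 4.05 in the female WT against 4.40 in the female KO library, so that KO replicate F1 lay below WT replicate 2. With WT replicate F1 and KO replicate 1 both left out and no sex term the median of the list was 0.22 (camera adjusted p = 0.00341). The mean of the cortex and hippocampus list followed a similar course, at 5.76, 5.84 and 5.38 in WT replicates 1, 2 and F1 and 6.28, 5.93 and 5.72 in KO replicates 1, 2 and F1.

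**Figure D2:**
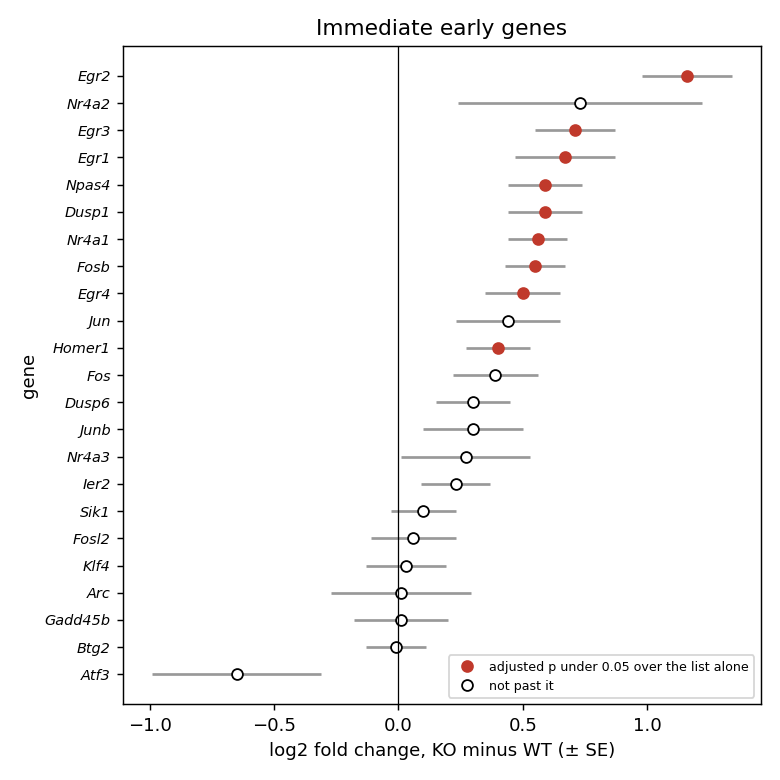
Log2 fold change (KO minus WT) with its SE for the 23 immediate early genes. Filled points mark the 9 genes past the threshold adjusted over the list alone, and the median of the list was 0.39.

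Lists for forebrain regions and synapses also passed with the preset correlation, higher in KO. All 13 tested genes of the cortex and hippocampus list had log2 fold changes above 0, with a median of 0.34 (camera adjusted p = 1.59e-04, adjusted p = 0.625 with an estimated correlation). Emx2 was at 9.52 and 13.2 CPM and Neurod6, a marker of excitatory forebrain neurons, at 66.4 and 91.6 CPM in WT and KO. All 12 genes of the striatum and bed nucleus list were above 0 (median 0.34, adjusted p = 0.00882, and 0.928 with an estimated correlation), with Drd2 at 54.2 and 77.5 CPM and Six3 at 22.9 and 43.2 CPM. Its median was 0.62 without WT replicate 1. Its call was lost with voom quality weights (0.21, adjusted p = 0.183), without KO replicate 1 (0.43, adjusted p = 0.0659) and in the contrast of the males, which is what remains without WT replicate F1 (median −0.07, adjusted p = 0.859) or KO replicate F1 (−0.07, 0.858). The list of glutamate release and receptors had 22 of 28 members above 0 (median 0.12, adjusted p = 0.00851, and 0.928 with an estimated correlation), among them the NMDA receptor genes Grin1 (0.29) and Grin2b (0.27). The list of presynaptic release machinery had 18 of 23 above 0 (median 0.10, adjusted p = 0.00988, and 0.625 with an estimated correlation), among them Syn1 (0.57) and Syt1 (0.30). With library totals alone, which shift the median of all genes to −0.17, the medians of these 2 lists were −0.05 and −0.07 and neither passed. The glutamate list did not pass without WT replicate 1 (median 0.10, adjusted p = 0.0523) or KO replicate 1 (0.11, 0.174), nor the presynaptic list without WT replicate 1 (0.10, 0.056) or in the contrast of the males, without WT replicate F1 (0.15, 0.105) or KO replicate F1 (0.15, 0.103), although these medians were about as large as with all libraries or larger. The presynaptic median was 0.16 without WT replicate 2. With WT replicate F1 and KO replicate 1 both left out, the medians of the cortex, striatum, glutamate and presynaptic lists were 0.02, 0.03, 0.05 and 0.06, and none of the 4 passed (adjusted p = 0.649, 0.738, 0.12 and 0.268). That fit has no sex term and its only female library is a KO library, so sex and genotype are mixed in it. With the mean of the cortex and hippocampus list as a covariate, which says nothing about that list itself, the striatum, glutamate and presynaptic calls were lost as well, with medians of 0.27, 0.01 and 0.03 (adjusted p = 0.722, 0.994 and 0.913), and the camera direction of the glutamate list turned.

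Transcripts of the energy and translation machinery differed as groups. All 13 mitochondrially encoded genes had log2 fold changes above 0, from 0.088 (SE 0.119) for mt-Nd3 to 2.23 (SE 1.29) for mt-Atp6, with a median of 1.06 (camera adjusted p = 4.98e-06, and 0.928 with an estimated correlation), which was 0.30 without KO replicate 1, the library with 20.63% mitochondrial counts. None of the 13 passed on its own in edgeR, over all genes or over the list alone, and 1 had an unadjusted p under 0.05; DESeq2 called 0 of them. mt-Co1 stood at 60264 CPM in that library and between 22399 and 30783 CPM in the other 5. Ribosomal protein genes had 29 of 31 members below 0 and a median of −0.27 (adjusted p = 6.06e-08, and 0.928 with an estimated correlation), but 0 passed in edgeR adjusted over the list alone. Rpl37 had a log2 fold change of −0.47 and Rps21 of −0.48, and the list median was −0.12 without KO replicate 1. Nuclear genes of oxidative phosphorylation were lower, with 24 of 30 below 0 (median −0.15, adjusted p = 0.00365, and 0.928 with an estimated correlation), Ndufa1 at −0.37 and Ndufa2 at −0.55. Without KO replicate 1 their median was −0.04 and the call was lost (adjusted p = 0.0854). With the cortex and hippocampus mean as a covariate the direction turned in all 3 lists. The mitochondrially encoded (median −0.46, adjusted p = 0.0765) and nuclear genes (0.12, 0.134) no longer passed, while the ribosomal genes passed in the opposite direction, higher in KO (0.16, 0.00408). With WT replicate F1 and KO replicate 1 both left out and no sex term the call of the nuclear genes was also lost (−0.02, 0.575).

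Genes of the microglial and chemotactic systems named in the title did not pass the test as groups. Of 25 homeostatic microglia genes 14 were above 0, with a median log2 fold change of 0.02 (camera adjusted p = 0.873). P2ry12, the purinergic receptor of resting microglia, stood at 16.1 ± 6.09 CPM in WT and 28.2 ± 5.65 CPM in KO (SD, n = 3 each; log2 fold change 0.86, SE 0.18, edgeR adjusted p = 0.735), and Sall1 at 31.6 and 42.1 CPM. DESeq2 called P2ry12, and the list passed, higher, with the mean of the cortex and hippocampus list as a covariate (median 0.31, adjusted p = 3.52e-04). Tmem119 (−0.19), Aif1 (−0.25) and Cx3cr1 (−0.30, 6.33 and 5.17 CPM) had log2 fold changes below 0, and none passed; Cx3cr1 overlaps other tested genes and is uncertain. Activated microglia genes had a median of −0.01 (adjusted p = 0.914), with Cd68 at 0.56 and Lpl at 0.38. The chemokine list had a median of 0.04 against a camera direction of lower (adjusted p = 0.914). Cxcl12, a chemokine that attracts lymphocytes and progenitors, stood at 74.9 ± 3.19 CPM in WT and 58.4 ± 8.81 CPM in KO (log2 fold change −0.37, SE 0.11, edgeR adjusted p = 0.735), and all 3 KO libraries lay below the WT libraries. Cx3cl1, the neuronal ligand of Cx3cr1 and a substrate of ADAM17, stood at 141 and 151 CPM (0.12). Ccl2 had 0, 5 and 11 counts in WT and 8, 17 and 3 counts in KO, and Ccl5 had 0, 5 and 10 counts and 5, 10 and 12 counts, too few to test. The list of chemokine and chemoattractant receptors had a median of 0.11 and a mean of −0.10 (adjusted p = 0.873), with the low-abundance receptor Fpr1 at −2.40. P2ry12, also a member, passed adjusted over this list alone (edgeR adjusted p = 0.036) but not over the homeostatic microglia list alone (0.0529). The list of cytokines and the NF-kB response had a median of −0.01 against a camera direction of higher (adjusted p = 0.694), with Ptgs2, the inducible cyclooxygenase, at 10.3 and 16.9 CPM (log2 fold change 0.69) and Tgfb1 at 0.35.

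The proteolytic and angiotensin lists likewise did not pass. ADAM17 substrates had a median log2 fold change of 0.01 (camera adjusted p = 0.914), with Tgfa at 36.3 and 58.2 CPM and Ngfr at 9.67 and 7.58 CPM in WT and KO. The WT mean of Tgfa was lowered by 8.59 CPM in WT replicate F1. It stood at 57.6 and 42.7 CPM in WT replicates 1 and 2 and between 50.2 and 70.3 CPM in KO. The list of ADAM17 regulators had a median of 0.00 (adjusted p = 0.873), with the kinase Mapk3 at 0.33. The renin-angiotensin list had a median of 0.07 (adjusted p = 0.873). Agt, the precursor of angiotensins, stood at 97.9 ± 51.7 and 65.5 ± 8.27 CPM, the WT mean being raised by 157 CPM in WT replicate F1, and the angiotensin receptor gene Agtr1a stood at 0.98 and 1.17 CPM. The chloride transporters that set the strength of GABA inhibition, Slc12a5 and Slc12a2, had log2 fold changes of −0.06 (SE 0.10) and −0.13 (SE 0.12), and the list of GABA and glycine inhibition had a median of 0.03 (adjusted p = 0.694). Astrocyte (−0.03), reactive astrocyte (−0.04), mature oligodendrocyte (−0.04), oligodendrocyte precursor (0.05), endothelial (0.02), pericyte (0.03), fibroblast (0.02) and perivascular macrophage (−0.04) lists had medians near 0 and did not pass. The lists of interferon response (0.07), class I antigen presentation (−0.13), complement (−0.03), antioxidant enzymes and NADPH oxidase (−0.12), heat shock (−0.04), glucocorticoid-induced genes (0.05), circadian clock (0.11), ependyma (−0.14), choroid plexus (0.01), thalamus (0.13) and red blood cells (−0.08) did not pass either. The clock genes with the smallest p were Npas2 (0.54) and Per1 (0.63), and neither passed over all genes. In the glucocorticoid list these were Hif3a (0.83) and Per1, and 1 member passed adjusted over that list alone. The blood leukocyte list had a median of −1.64 (adjusted p = 0.113), where the neutrophil gene Ngp stood at 30.8 CPM in WT replicate 1 and between 0.44 and 2.87 CPM in the other 5 libraries.

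**Figure D3:**
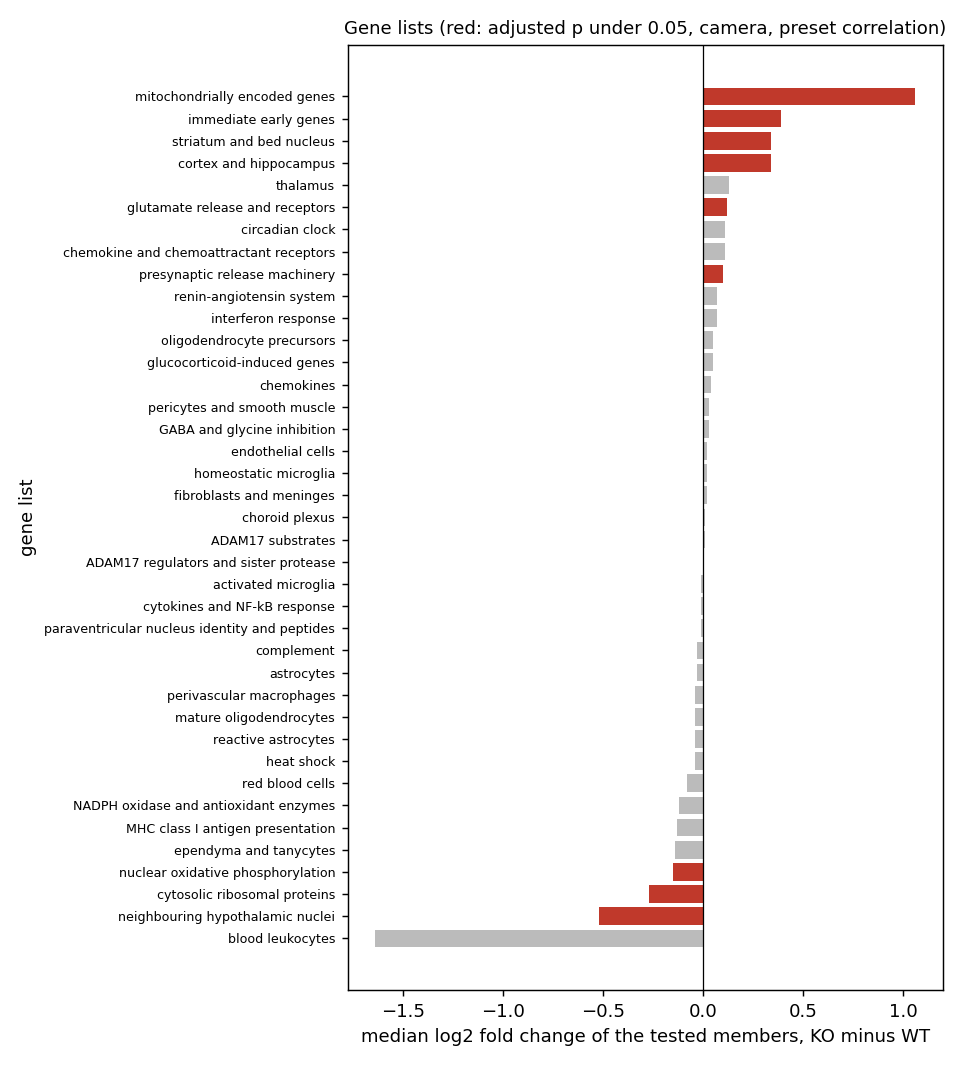
Median log2 fold change (KO minus WT) of the 39 gene lists tested. Red bars mark the 9 lists past the threshold in camera with the preset correlation, from −0.52 for neighbouring hypothalamic nuclei to 1.06 for mitochondrially encoded genes.

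Genes that identify the paraventricular nucleus varied between libraries of the same genotype. Avp, which encodes vasopressin, stood at 27.7, 5.96 and 38.2 CPM in WT replicates 1, 2 and F1 and at 5.25, 8.34 and 13.8 CPM in KO replicates 1, 2 and F1 (log2 fold change −1.36, SE 0.56, edgeR adjusted p = 0.735). Oxt, which encodes oxytocin, stood at 19.4 ± 11.9 and 9.14 ± 5.62 CPM (−1.17, SE 0.58), and Crh at 6.92 ± 1.26 and 7.69 ± 0.48 CPM (0.17, SE 0.14). The list of paraventricular identity genes and peptides had a median of −0.01 (camera adjusted p = 0.694), with Penk at 0.62 and Cartpt at −0.48. Genes of neighbouring hypothalamic nuclei were lower in KO, with 20 of 24 below 0 and a median of −0.52 (camera adjusted p = 0.029, and 0.928 with an estimated correlation), although the members with the smallest p, Npy (0.45) and Lhx6 (0.36), were higher. That call was lost without WT replicate 1 (median −0.30, adjusted p = 0.313) or KO replicate 2 (−0.28, 0.689), in the contrast of the males, without WT replicate F1 (−0.53, 0.166) or KO replicate F1 (−0.53, 0.175), with library totals alone (−0.74, 0.33) and with a filter at a mean of 1 CPM (−0.38, 0.334). Without KO replicate 1 the median was −1.08. Slc17a6, the vesicular glutamate transporter of hypothalamic neurons, stood at 82.5 ± 37.8 CPM in WT and 69.1 ± 39.1 CPM in KO (−0.17, SE 0.51), while Slc17a7, the transporter of cortical neurons, stood between 662 and 1019 CPM. The ratio of Slc17a7 to Slc17a6 was 14.9, 11.6 and 5.39 in WT replicates 1, 2 and F1 and 5.94, 29.8 and 12.9 in KO replicates 1, 2 and F1.

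**Figure D4:**
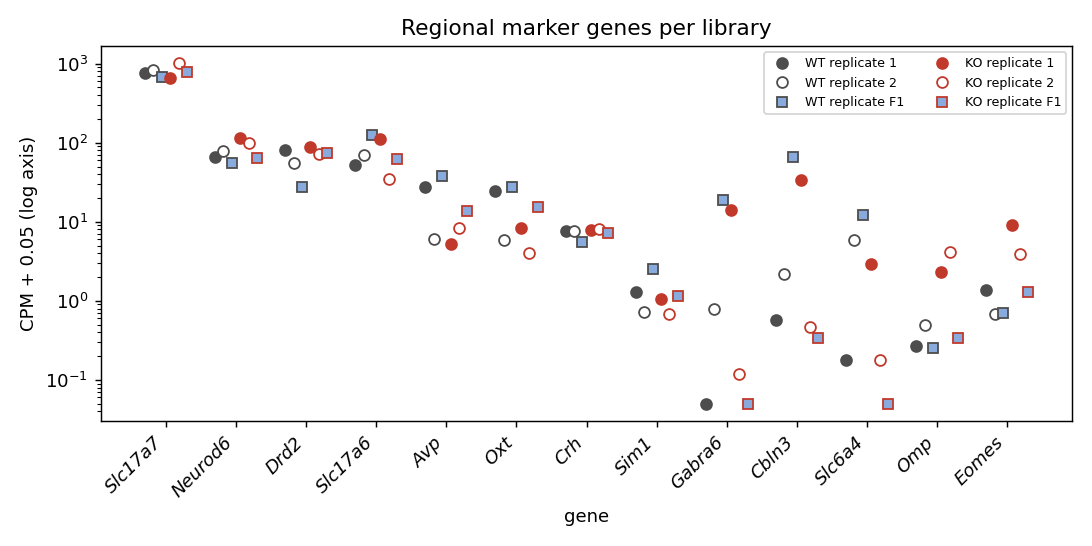
CPM plus 0.05 on a log axis for marker genes of brain regions in each library. Slc17a7 lies between 662 and 1019 CPM and Slc17a6 between 34.2 and 125 CPM, and Gabra6 and Cbln3 stand out in WT replicate F1 and KO replicate 1.

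The 2 female libraries differed from the 4 male libraries in sex-linked genes, as a second labelled factor. Xist, the RNA that silences an X chromosome, averaged 605 CPM in females and 0.22 CPM in males, and the Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty averaged 19.8, 24.2, 38.8 and 12.7 CPM in males and at most 0.025 CPM in females. With these 5 genes, 3 processed pseudogenes passed, all higher in females, namely Gm9825 (20.1 against 1.10 CPM), Gm6311 and Rps2-ps13, which were named after their values were seen and whose reads cannot be separated with certainty from those of related copies. In all, 8 of 18956 genes passed in edgeR, 4 higher and 4 lower in females, and DESeq2 called 56. Without WT replicate F1, KO replicate 1 or KO replicate F1 the counts were 14, 13 and 25. Of the gene lists, 16 passed with the preset correlation, 9 higher and 7 lower in females, and 0 passed with estimated correlations. The choroid plexus list was lower in females (median log2 fold change female minus male −0.79, camera adjusted p = 7.26e-10, and 0.575 with an estimated correlation), as was the immediate early list (−0.30, adjusted p = 1.12e-07, and 0.329 with an estimated correlation). The cortex and hippocampus list (−0.38, adjusted p = 2.92e-06, and 0.393 with an estimated correlation) and the striatum and bed nucleus list (−0.42, adjusted p = 0.00325, and 0.66 with an estimated correlation) were lower in females too. Median CPM of the choroid plexus list was 2.75 in WT replicate F1 and 3.36 in KO replicate F1, against 3.24 to 5.91 in males. For the striatum list it was 51.1 and 90.4, against 77.6 to 103. In both lists only the median of WT replicate F1 lay below all males, and the lower striatum values rest mainly on that library. Single choroid plexus genes could be lower in both females. Ttr stood at 135 CPM in WT replicate F1 and 289 CPM in KO replicate F1, against 359 to 667 CPM in males. For the cortex list median CPM was 51.8 and 75.9, against 70.0 to 98.9, while mean log2 CPM was 5.38 and 5.72, against 5.76 to 6.28. The endothelial list was higher (0.22, adjusted p = 6.45e-05, and 0.329 with an estimated correlation). Its median CPM was 27.8 in WT replicate F1 and 32.6 in KO replicate F1, against 22.7 to 24.1 in males.

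The test for a genotype effect that differs between the sexes rests on 1 female library per genotype, so its spread comes from the male libraries alone. It called 14 of 18956 genes, 11 with a higher and 3 with a lower KO effect in females (edgeR, lowest adjusted p = 0.00355). Among them 4 belong to the protocadherin beta and gamma clusters on chromosome 18 and 8 are gene models without a proper name. Pcdhgb4, a cell adhesion gene, stood at 237 CPM in WT replicate F1 and between 6.94 and 11 CPM elsewhere, and Pcdhga1 at 130 CPM in KO replicate F1 and between 5.81 and 8.82 CPM elsewhere. These genes overlap other members of their cluster, so their counts are uncertain. Single male libraries held such values too, with Pcdhgb1 at 283 CPM in WT replicate 1 and Pcdhgb8 at 206 CPM in KO replicate 1.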

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

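In this part the test around the Adam17 locus, the separate count of splits by the side of the females and the splits without a sex term were chosen after the values had been seen. The count of 14 genes whose KO effect differed between males and females stands out because it tests the difference itself, and it rests on a single female library per genotype. The interaction log2 fold change was −5.59 for Pcdhgb4, 4.10 for Pcdhga1, 10.23 for Gm12191 and 7.70 for Erdr1. Erdr1 was at 0.02 CPM in WT replicate F1, under the floor of that library, so its fitted value depends on the prior count and is no measure of size. Gm12191 stood at 15.4, 16.0 and 15.6 CPM in WT replicates 1, 2 and KO replicate F1 and between 0.42 and 0.51 CPM in the other libraries. Among the 14 genes, 5 (Gm12191, Gm4202, Mir686, Rpl30-ps9 and Rpl30-ps10) separate these same libraries at least 2-fold, and they lie on chromosomes 11, 3, 14, X and X.

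Genes that are present in some libraries and nearly absent in others were weighed against several explanations. The summed level of the 22 tested protocadherin gamma genes differed by only 1.34 times between the highest and lowest library, while 8 single members differed over 10-fold, which is consistent with reads of shared exons being assigned to different overlapping members. Between all KO and all WT libraries 8 genes, Noct among them and none from that cluster, had a gap of 2-fold or more, and another split of the libraries gave 12, so differences between mice or dissections that do not follow genotype could give such genes. Adam17 lies on chromosome 12, whereas the 8 genes lie on chromosomes 3, 7, 9, 14 and 18, and none of the 14 interaction genes lies on chromosome 12. A segment carried along with the modified locus therefore holds none of these genes, which argues against it as their direct source. For other genes it stays undecided. Of the 93 genes within 10 Mb of Adam17, 7.5% had p under 0.05 against a median of 5.4% in windows of as many genes, too little to decide whether such a segment contributes there. An effect of the genotype on Noct stays open and has no independent test here.

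The split of the 6 libraries by genotype gave 1 gene, and another split gave 431. In total 5 of the 10 splits gave at least as many genes, and 10 splits are too few for a share under 0.05. The 431 genes do not compare 3 libraries with 3. Both females lie on one side of that split, so the sex term absorbs them and KO replicate 1, the library with 20.63% mitochondrial counts, stands alone against the other male libraries. A single male library stands alone in this way in 4 of the 10 splits. In the 6 splits with the females on opposite sides, the real one included, the highest other count was 5 genes and 3 gave at least as many as the real split. Without the sex term the real split gave 3 genes and the highest other 9. The splits with 5 and with 9 genes both put the male WT libraries and the female KO library on one side, which is the crossing of genotype and sex, so they restate the interaction above and are no separate evidence. For gene lists the real split gave 9 and the highest other split 21, with the females on opposite sides. At least as many lists came from 7 of the 10 splits, and from 5 of the 6 with the females on opposite sides. The immediate early list passed in the real split (camera adjusted p = 4.31e-08) and in other splits too, at 0.00362, 0.00167, 0.00587 and 3.58e-05. Of these, 0.00167 and 0.00587 came with the females on opposite sides. In the remaining splits its adjusted p was 0.249 to 0.525. The real split gave the smallest value.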

How the results depend on the processing

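The alternatives with WT replicate F1 and KO replicate 1 both left out, without mitochondrial genes and with the cortex and hippocampus covariate were chosen after seeing the data. The first of these has no sex term, and its only female library is KO replicate F1. Adam17 stayed below 0 (log2 fold change −0.16 to −0.35) and was not called in any of 16 settings. Noct kept a log2 fold change of 1.83 to 2.09 and its call in 11 of 16. Without either female the genotype contrast is that of the males, so these fits and the males alone count once. The KO versus WT count, 1 as designed, was 4 without a filter on low counts, 4 with voom quality weights, 4 with limma-trend on TPM, 75 with DESeq2, 3 without the sex term, 18 in males only, 27 with WT replicate F1 and KO replicate 1 left out and 0 with the cortex covariate, which uses up a degree of freedom (Noct 1.90, adjusted p = 0.552). Leaving out 1 library gave 0 to 20 genes. The female versus male count, 8, was 13 without a filter, 56 with DESeq2 and 6 to 25 leaving out 1 library, where a lone remaining female is assumed to vary like the males. The lists past the threshold numbered 0 with estimated correlation and 0 with fry, 6 to 12 leaving out 1 library, and the immediate early list kept its call in 15 of 17 settings. The interaction count was 14 as designed and in the 2 alternatives run, a filter on mean expression and RLE size factors; it was not refitted leaving out libraries. With the replicate number as a block, 0 genes passed (Noct 2.0, adjusted p = 0.0572) and 10 lists did. Libraries of the same number correlated at −0.11, −0.04 and −0.08 in their deviations, no library correlated best with its own number, and the numbers were not taken as pairs. With the cortex covariate the camera direction of several lists turned, with medians of 0.54 for perivascular macrophages, 0.45 for fibroblasts, 0.01 for glutamate, −0.26 for GABA, −0.66 for thalamus, −0.46 for mitochondrially encoded, 0.12 for oxidative phosphorylation and 0.16 for ribosomal genes, and with WT replicate F1 and KO replicate 1 left out fibroblasts gave 0.31. A turn between values that passed in neither fit was not counted as a reversal; there were 116 among 1297 single values. The causes were not tested. A second pseudocount was not run because counts were at hand. Ccl2 and Ccl5 were too low to test at this depth.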

Other observations

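Libraries differed in markers of brain regions that lie far from the hypothalamus. The cerebellar granule cell gene Gabra6 stood at 18.9 CPM in WT replicate F1 and 13.9 CPM in KO replicate 1, and at most at 0.75 CPM in the other 4, and Cbln3 followed with 65.5 and 33.5 CPM. The serotonin transporter gene Slc6a4 stood at 12.2 CPM in WT replicate F1, 5.79 CPM in WT replicate 2 and 2.88 CPM in KO replicate 1, and at most at 0.13 CPM elsewhere. The dopamine transporter gene Slc6a3 stood at 40.8 CPM in WT replicate F1, 10.1 CPM in KO replicate 2 and at most at 5.04 CPM elsewhere. Omp, Eomes and Cdhr1, expressed in the olfactory system, had log2 fold changes of 2.52, 2.15 and 1.63, with Eomes at 9.14 and 3.87 CPM in KO replicates 1 and 2 and between 0.64 and 1.33 CPM elsewhere. Omp stood at 2.29 and 4.07 CPM in KO replicates 1 and 2 and at 0.29 CPM in KO replicate F1, against 0.20 to 0.45 CPM in WT, so the higher values of Omp and Eomes rest on KO replicates 1 and 2. Cdhr1 stood at 56.4, 42.7 and 30.0 CPM in KO replicates 1, 2 and F1 and at 12.3, 8.64 and 23.1 CPM in WT replicates 1, 2 and F1. The genes of these regions were picked after their values had been seen, so they allow no test of a difference between the genotypes.

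Xaf1, an interferon-inducible gene, stood at 24.0 and 12.8 CPM in KO replicates 1 and 2 and between 3.53 and 4.69 CPM elsewhere. Nnt, a mitochondrial transhydrogenase whose gene is deleted in part in some inbred mouse strains, stood at 28.4 CPM in KO replicate 1, 7.16 and 8.43 CPM in WT replicates 1 and 2, and 3.80, 2.01 and 1.25 CPM in WT replicate F1, KO replicate 2 and KO replicate F1. In the side column of channel and transporter symbols, 174 of 220 were tested and 0 passed in edgeR, with 6 higher and 4 lower at an unadjusted p under 0.05. The list as a whole had a median log2 fold change of −0.01 and did not pass in camera either. Kctd1 and Scnn1a had log2 fold changes of 0.67 and 0.59.

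The ratio of Slc17a7 to Slc17a6 was 5.39 or more in every library, and the median of the cortex and hippocampus list, 51.8 to 98.9 CPM, exceeded that of the paraventricular list, 9.63 to 23.3 CPM, in all 6. These values prompted the explanation of tissue from outside the nucleus in every library and compare levels of different genes, so they do not test it. It stays open, and no biological explanation was tested.

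The higher immediate early list may have several origins. Without KO replicate 1, the library rich in mitochondrial transcripts, the median was 0.39, as with it (camera adjusted p = 1.38e-07), which counts against that library alone as the cause. With the cortex and hippocampus mean as a covariate the median was 0.34, 0.87 of its value without it, and the list still passed with the preset correlation (adjusted p = 3.68e-04, with a range over all alternatives of 3.94e-10 to 0.574). The bootstrap interval over genes, 0.19 to 0.47, reaches below the bound set in advance, so this test does not decide whether more forebrain tissue is the whole cause. The spread between libraries leaves it open too. With 1 mean of log2 CPM per library, a fit chosen after the values had been seen, KO minus WT was 0.34 (95% interval 0.14 to 0.54) with genotype and sex, 0.31 (−0.27 to 0.90) with the covariate added, 0.35 (−0.02 to 0.72) without KO replicate 1, and 0.16 (−0.75 to 1.07) with WT replicate F1 and KO replicate 1 both left out. The last of these fits has no sex term and its only female library is a KO library, so sex and genotype are mixed in it. More forebrain tissue in the KO libraries therefore cannot be told apart from an effect of genotype. The genotype effect stays among the open explanations, as untested, and the call does not hold with an estimated correlation. Splits of the libraries that do not follow genotype gave a call of this list too.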
